A study of Mus musculus with 20 samples.

How the data were processed

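RNA from 12 libraries and DNase-accessible chromatin from 8 libraries of sorted mouse CD4 T cells were analysed, 2 libraries in each of 10 groups. Groups were taken from the sample titles. RNA was selected for polyadenylated transcripts, per the labels' protocols. The deposited RNA tables give whole-number read counts and RPKM for each of 29257 RefSeq transcript rows, with one library per table. The authors' RPKM, deposited beside the counts, are reads per kilobase of transcript scaled to a total of each library. In the spleen tables the header words for count and length are swapped. The column used as counts there is the one that, divided by transcript length, is proportional to RPKM, and the column used as length is identical in all 12 RNA tables. The counts were used as deposited. Per the submitters' processing notes the tools were CASAVA 2.18, Bowtie2, SICER 1.1 and edgeR, with genome build mm9; which step used which tool is not given in the sources used here. The DNase files hold islands with a score, the authors' own value for each island as deposited. Per the deposited file names, duplicates were removed and islands were called in each library with a window of 200 bp, a gap of 400 bp and an E-value of 1. The scores were used only to rank or filter islands within a library.

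For each of 22878 gene symbols the transcript row with the most reads over the RNA libraries was kept, since 4019 symbols had more than 1 row. Reads of paralogs and overlapping genes may be split or shared by the authors' counting, and whether strand was used is not given in the sources used here. Symbols were looked up in current name tables, where 20722 were found and 1964 more matched an older synonym. Gene count totals ran from 13169783 to 24174592. The floor of 3 reads per library covers counting error only. Where a group had no reads, list medians were also computed with that gene at its bound against this floor.

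Counts were tested with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjusted p below 0.05. The 4 spleen libraries were fitted alone. The 8 lymph node libraries were fitted together with one mean per group, and 4 pairwise contrasts and the interaction were tested. Fold changes are on the log2 scale. The standard error beside each is its absolute value divided by the square root of the F statistic. For genes with a group at or near 0 reads, the fold change depends on the prior count, and this error does not cover that. RPKM are given as mean and SD of 2 libraries. Gene lists were tested with camera (preset correlation 0.01, and estimated) and fry in limma 3.58.1, adjusted over the 23 lists of a comparison. With an estimated correlation camera uses the residual degrees of freedom of the fit, 2 in the spleen and 4 in the lymph node. A call lost in that setting can therefore come from few libraries as well as from correlated genes. The 23 lists were Th1 and cytotoxic effector, Tfh, Th2, Th17, Treg, naive and central memory, non-Tfh effector and migration, cell cycle, T cell receptor activation and immediate early, type I interferon response, interferon gamma response, inhibitory receptors, glycolysis, cholesterol synthesis, CD4 T cell identity, and markers of B cells, plasma cells, macrophages and monocytes, dendritic cells, neutrophils, CD8 T cells, NK and innate-like T cells and erythroid cells. Overlaps of calls were tested with Fisher's exact test, two-sided, adjusted over 12 tests. The groups, tests, gene lists, named-gene rule and most alternatives were fixed before the data were examined.

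Genes named in every RNA comparison were Tbx21, Ifng, Bcl6, Cxcr5 and Pdcd1. Further names were drawn from the 8 largest rises and 8 largest falls among called genes whose groups do not overlap and whose higher mean is at least 5 RPKM, and from up to 3 members of each list with the smallest adjusted p. Genes shared by overlaps of 13 or fewer, marker genes of other cell types given for their levels, and called members counted within a list were named after their values were seen. Gene models without a protein name were left out of the largest changes, and some genes that the rule names are not reported here. For the interaction some of the 10 genes with the smallest adjusted p were named.

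DNase islands were compared as island number, covered length, Jaccard index over 200-bp bins, and merged regions private to a group, where an overlap of 1 bp counted as shared. Exact permutation tests used all 70 arrangements of the 8 libraries, all 105 pairings or, for the interaction, 36 arrangements. Positions are 1-based on mm9. No gene positions on mm9 were used, so the planned look at islands of the Ifng locus and of regions near changed genes was not run.

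Alternatives were DESeq2 1.42.0 (Wald test), limma-trend on log2(RPKM + 1) for genes with at least 1 RPKM in 2 libraries (the pseudocount 0.1 also tried), median-of-ratios factors, no filter, a filter of 5 RPKM, the replicate number as a block, the 4 compared libraries alone, each library left out in turn, and for islands the 10000 highest scores, scores above the median and coverage of at least 0.5 of a region. Added after the data were seen were the longest transcript row, the lymph node without both Tomato- replicate 2 libraries, and leaving out libraries for lists, overlaps and island statistics. On data simulated with 200 changed genes, edgeR recovered 82.1% of 2-fold and 100% of 4-fold changes in the spleen design, with 11 false calls among 199. In the Tfh Tomato design it recovered 0% of 2-fold, 16.4% of 4-fold and 45.5% of 16-fold changes with 2 false calls, and in the non-Tfh Tomato design 0%, 17.9% and 51.5% with 2 false calls. DESeq2 made 96 and 97 false calls in these designs, and 47 and 67 where nothing was changed. Each setting was simulated once, with the dispersion of edgeR's fitted trend for every gene and no spread of single genes around it. The simulation therefore follows edgeR's own model, and its false call counts may not carry over to the real data. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 was used for the DNase work and figures.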

Results

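The series holds 20 libraries from mouse CD4 T cells sorted by present or past expression of T-bet, the transcription factor encoded by Tbx21 that directs T helper 1 (Th1) differentiation. In the spleen of naive mice, CD44-high CD25-negative cells that carried tdTomato, a permanent mark of T-bet expression, were split by ZsGreen, a reporter of current T-bet expression. In the draining lymph node on day 16 after immunization with the AS15 peptide, tetramer-positive cells were split into follicular helper T cells (Tfh, CXCR5-high PD1-high) and other cells (non-Tfh, CXCR5-low PD1-low), and each by Tomato, a mark of T-bet expression that can be present or past. Polyadenylated RNA was sequenced in 6 groups and DNase-accessible chromatin in 4 groups, with 2 libraries in each group. Total counts over genes ranged from 13169783 in non-Tfh Tomato- replicate 2 to 24174592 in spleen ZsGreen+ replicate 1. Reads were found for 15080 to 15326 genes in the spleen libraries and for 11154 to 11805 genes in the lymph node libraries. Nothing in the labels says that replicates came from separate animals, so p-values of the gene tests measure the spread between these samples, which may be technical. Other p-values rest on other units. The overlap tests count genes, and camera with its preset correlation sets list members against the other genes. Small values from them are not evidence from replicates. The permutation tests of islands rearrange libraries. The common biological coefficient of variation between replicates was 0.0867 in the spleen and 0.908 in the lymph node.

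The first comparison sets spleen cells that carry the T-bet reporter beside cells that carry the mark of past T-bet expression without the reporter. The ZsGreen- cells still held Tbx21 transcripts. Tbx21 itself was 4.32-fold higher in splenic ZsGreen+ cells (203.6 ± 14.5 RPKM) than in ZsGreen- cells (45.9 ± 0.760 RPKM; SD, n = 2). ZsGreen reports T-bet expression, so the direction of this difference followed from the gate. Ifng, the gene of the Th1 cytokine interferon gamma, was 3.11-fold higher, at 33.9 ± 2.67 against 10.6 ± 0.268 RPKM. The Tfh regulator Bcl6 was 2.17-fold lower, the follicle-homing receptor Cxcr5 was 5.54-fold lower and Pdcd1, which encodes the inhibitory receptor PD1, was 3.49-fold lower. Among genes of at least 5 RPKM in the higher group, the largest rise was that of the chemokine gene Xcl1, with a log2 fold change of 5.36 ± 0.18 (SE), with further rises of Slc27a6 (5.34 ± 0.30), Atp8a2 (5.06 ± 0.19), the water and glycerol channel gene Aqp9 (4.89 ± 0.22) and Prrt1 (4.88 ± 0.33). The chemokine receptor gene Cxcr6 rose by 4.11 ± 0.13 and reached 606 ± 106 RPKM. The largest falls among them were those of Sostdc1 (-4.42 ± 0.40), Actg2 (-4.05 ± 0.18), Tox2 (-3.69 ± 0.12), Bambi-ps1 (-3.19 ± 0.23) and Gpr83 (-3.16 ± 0.18). In all, 3074 of 12918 tested genes changed (edgeR quasi-likelihood test, adjusted p below 0.05), 1470 of them higher and 1604 lower in ZsGreen+ cells. Among these, 1061 differed by at least 2-fold.

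Of the 30 genes of the fixed Th1 and cytotoxic effector list, 23 rose in splenic ZsGreen+ cells, 1 fell and 6 did not pass; adjusted over the list alone, 25 rose and 1 fell. The pore-forming protein gene Prf1 rose 8.58-fold and the granule gene Nkg7 6.42-fold. All 11 tested NK and innate-like T cell markers rose (adjusted over the list alone, also 11), among them the innate-like T cell regulator Zbtb16 by 3.79 ± 0.13 and the NK receptor genes Klrk1 by 3.55 ± 0.11 and Klrb1c by 3.71 ± 0.14. These values cannot tell a change within the cells from a different share of innate-like T cells in the ZsGreen+ sort, which was not tested. Of 25 tested Tfh genes 22 fell, including Id3 (-2.89 ± 0.08), and 1 rose (over the list alone, 22 and 2). The member that rose, Il4, encodes a Th2 and Tfh cytokine and went from 4.56 ± 1.40 to 42.3 ± 5.72 RPKM. Regulatory T cell (Treg) genes fell in 8 of 12 cases and rose in 2 (over the list alone, 9 and 2), with Foxp3, the Treg lineage factor, lower by 2.73 on the log2 scale (log2 fold change -2.73 ± 0.10). In the Th17 list 5 of 8 genes fell, among them Ccr6 (-3.13 ± 0.15), and 1 rose (over the list alone, 5 and 1). In the Th2 list 3 of 6 fell, such as Ccr4 (-1.90 ± 0.10), and 1 rose (over the list alone, 4 and 2).

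Cholesterol synthesis genes fell in 12 of 19 cases in splenic ZsGreen+ cells and rose in 1 (over the list alone, 14 and 1), with Sqle at -1.52 ± 0.11. Cell cycle genes fell in 18 of 30 cases and rose in 2 (over the list alone, 21 and 4), with the proliferation marker Mki67 at -0.57 ± 0.08. Interferon gamma response genes rose in 12 of 17 cases and none fell (over the list alone, 13 rose), for example the signalling inhibitor Socs1 at 0.99 ± 0.10. Of the naive and central memory genes 8 of 13 fell and 3 rose (over the list alone, 8 and 3), with the lymph node homing receptor Ccr7 at -2.05 ± 0.11 and the interleukin 7 receptor gene Il7r at 1.25 ± 0.07. Of the non-Tfh effector and migration genes 13 of 20 fell and 4 rose (over the list alone, 14 and 4), the receptor Ccr2 rising by 2.16 ± 0.08. Inhibitory receptors went both ways: 6 of 10 fell, such as Ctla4 (-2.46 ± 0.14), and 3 rose, such as Cd160 (3.31 ± 0.11), with the same counts over the list alone. In the CD4 T cell identity list 7 of 13 fell and 1 rose (over the list alone, 8 and 1), Cd4 itself at -0.98 ± 0.08. Among dendritic cell markers 3 of 10 rose, Ccr9, Xcr1 and Itgax (over the list alone, 3); Ccr9 is also a gut-homing receptor of T cells. The set test camera called these 14 lists with its preset correlation, at adjusted p from 8.61e-55 for the Th1 list to 0.0111 for inhibitory receptors. None held with an estimated correlation: the adjusted p with an estimated correlation was 0.0705 for the Th1 list, 0.127 for the NK and Treg lists, 0.174 for the Tfh, Th17, cholesterol and dendritic lists, 0.186 for CD4 identity, 0.231 for Th2, 0.301 for the naive, 0.334 for the inhibitory, 0.39 for the interferon gamma, 0.532 for the cell cycle and 0.584 for the non-Tfh effector list. That setting uses 2 residual degrees of freedom here. The estimated correlation lay below the preset 0.01 for Th1 (-0.0197) and Treg (-0.0763), among others, and above it for cell cycle (0.385), among others. Not called were immediate early genes (camera adjusted p 0.257; median 0.05, mean -0.11, test direction down), type I interferon response (0.0827), glycolysis (0.879; median -0.04, test direction up), B cell markers (0.907), plasma cell markers (0.475), macrophage and monocyte markers (0.149), neutrophil and granule markers (0.0907), CD8 markers (0.51) and erythroid markers (0.628). Single members of these lists passed: 5 immediate early genes rose and 8 fell (over the list alone, 6 and 8), 6 type I interferon genes rose and 1 fell (7 and 1), 3 glycolysis genes rose and 2 fell (3 and 2), and Cd22 and Igj fell among B cell and plasma cell markers (1 each over the list alone). Of the macrophage and monocyte markers 4 of 15 rose (over the list alone, 6 rose and 1 fell), Itgam, Fcgr3, Mpeg1 and Lyz2, and of the neutrophil markers Cxcr2 rose (over the list alone, 3). The calls of Itgam, Fcgr3, Cxcr2 and Cd22 were each lost without 1 of the 4 libraries. Transcripts of myeloid cells were present in all 4 spleen libraries: S100a8, a neutrophil gene, measured 392 to 610 RPKM and Lyz2, a macrophage gene, 187 to 312 RPKM.

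**Figure D1:**
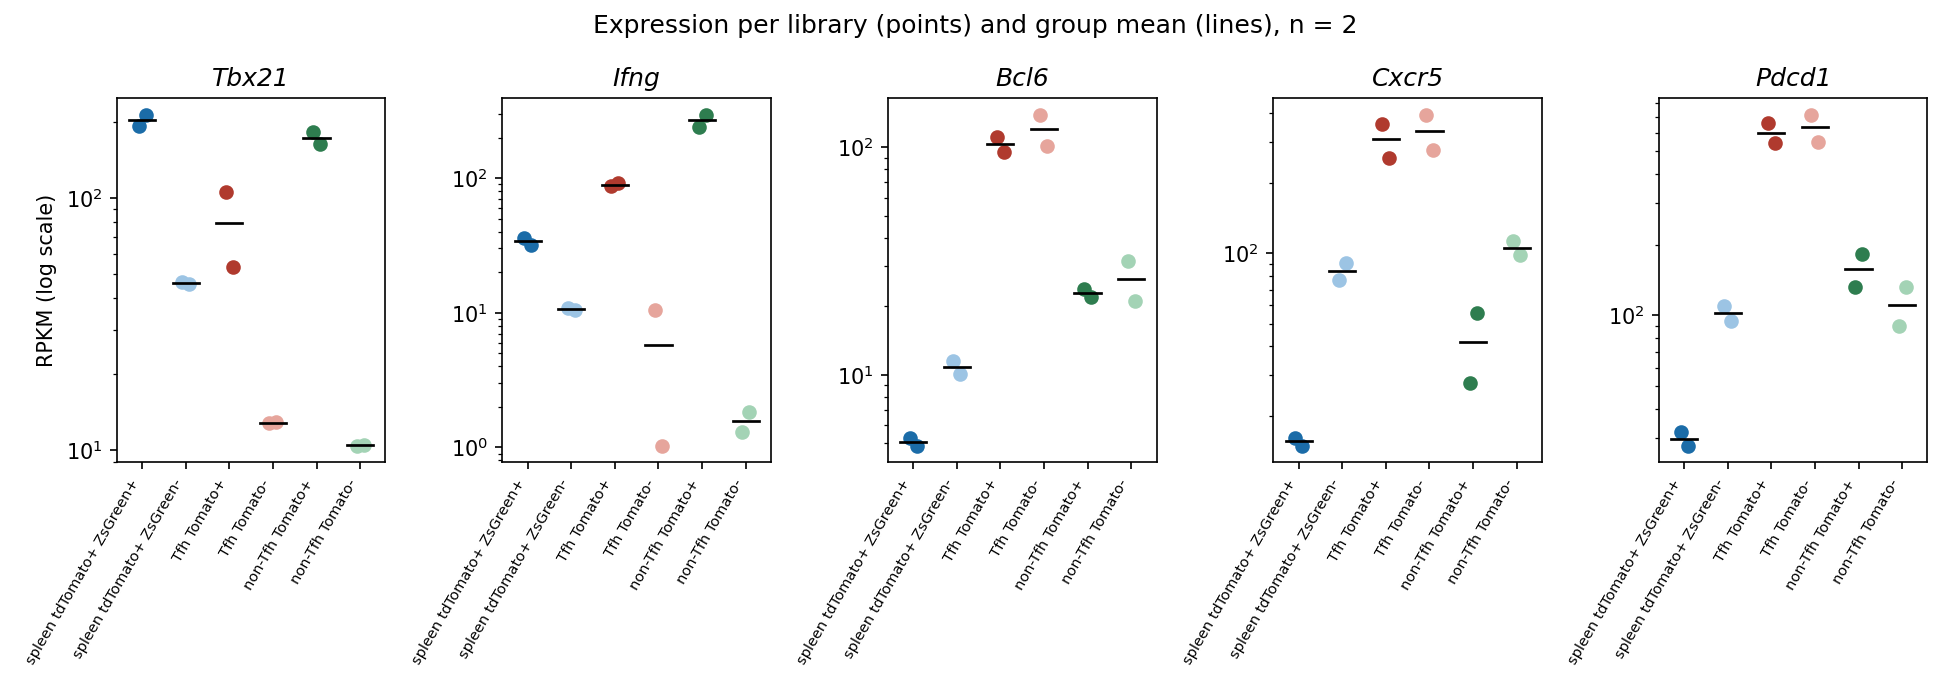
RPKM on a log scale of Tbx21, Ifng, Bcl6, Cxcr5 and Pdcd1 in each RNA library (points) with the mean of each group (lines, n = 2). Tbx21 averaged 203.6 RPKM in spleen ZsGreen+ cells and 173.0 RPKM in non-Tfh Tomato+ cells, and 10.4 RPKM in non-Tfh Tomato- cells.

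The question in the lymph node was how present or past T-bet expression relates to expression in Tfh and non-Tfh cells of the same response. The labels name no reporter of current expression for these cells, so Tomato+ cells can include cells that still expressed T-bet. Tomato marks T-bet expression, so higher Tbx21 in Tomato+ cells is not an independent result. In Tfh cells Tbx21 was 6.16-fold higher with Tomato (79.4 ± 37.5 against 12.8 ± 0.0745 RPKM; adjusted p = 0.0442, edgeR). Ifng was at 89.3 ± 2.88 RPKM in Tomato+ and 5.75 ± 6.67 RPKM in Tomato- Tfh cells, a 15.3-fold difference that did not pass (adjusted p = 0.326; 4.7e-06 to 0.692 over the alternatives). Its log2 fold change of 3.93 became 6.41 without Tomato- replicate 1, where it passed (adjusted p = 0.0123), and 3.07 without Tomato- replicate 2. It also passed with DESeq2 and with limma, though not with a limma pseudocount of 0.1. The membrane protein gene Emp1 rose by 7.39 ± 0.75, the interleukin 18 receptor subunit gene Il18rap by 6.00 ± 0.77, Nkg7 by 3.45 ± 0.29, the cytokine signalling inhibitor Cish by 3.27 ± 0.31, the galectin gene Lgals3 by 2.91 ± 0.30, Ahnak by 2.53 ± 0.25 and the protease gene Furin by 2.13 ± 0.28. Il1b, a cytokine gene of myeloid cells, fell by 6.87 on the log2 scale (log2 fold change -6.87 ± 0.84). Bcl6 (-0.24 ± 0.26), Cxcr5 (-0.13 ± 0.35) and Pdcd1 (-0.09 ± 0.27) did not pass. In all, 13 of 11746 genes changed, 12 higher and 1 lower. The count was 3 without Tomato+ replicate 1, 8 without Tomato+ replicate 2, 6 without Tomato- replicate 1 and 2 without Tomato- replicate 2. With edgeR on the 4 compared libraries alone it was 0, with 729 genes at an unadjusted p below 0.05. Without the Tomato- replicate 2 libraries of both populations, in which neutrophil transcripts were high (S100a8 299.9 RPKM here, 9.70 RPKM in replicate 1), it was 0 as well, with 759 at an unadjusted p below 0.05. With all 8 libraries limma called 29 genes and DESeq2 262. No call of a named gene was kept in all 4 fits that left out 1 library: Nkg7 and Cish were kept in 3, Emp1, Lgals3 and Ahnak in 2, Tbx21, Crip1 and Il1b in 1 and Il18rap, Furin and Selplg in 0.

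In the non-Tfh effector and migration list 5 of 20 genes rose with Tomato in Tfh cells (adjusted over the list alone, 14), among them Crip1 (2.11 ± 0.21) and Selplg, the P-selectin ligand gene (1.51 ± 0.15). In the Th1 list 3 of 30 rose (over the list alone, 10). No single member passed over all genes in the other 21 lists. Camera called 9 lists: Th1 (median 1.098), non-Tfh effector (1.46), NK markers (3.18, or 3.16 with genes at 0 in a group set to their bound) and cell cycle (1.004) upward, and Tfh (-0.29), type I interferon response (-0.47), B cell markers (-0.71), macrophage and monocyte markers (-1.76) and neutrophil markers (-6.18) downward. Calls were lost at adjusted p with an estimated correlation of 0.144 for cell cycle and for type I interferon response, 0.211 for Tfh, 0.0648 for B cell markers and 0.493 for neutrophil markers. The Th1 and non-Tfh effector lists (adjusted p = 0.00693 each), NK markers (0.0345) and macrophage markers (0.035) held with an estimated correlation. Over the list alone 3 NK markers rose, 4 B cell markers fell and 1 macrophage marker fell, and none of the cell cycle, Tfh, type I interferon or neutrophil genes passed. Among lists not called, 1 Treg, 1 naive, 1 interferon gamma response and 1 dendritic cell gene rose and 1 Th17 and 1 dendritic cell gene fell over the list alone. Lyz2 was at 222 ± 31.5 RPKM in Tomato+ and 746 ± 114 RPKM in Tomato- Tfh cells. The MHC class II gene H2-Ab1, of antigen-presenting cells, was at 258 ± 14.3 and 769 ± 271 RPKM. The camera adjusted p of the 14 lists not called ran from 0.053 for Treg genes to 0.816 for cholesterol synthesis and CD8 markers. They were Th2 (0.74), Th17 (0.74), Treg, naive (0.816), immediate early (0.816), interferon gamma response (0.74), inhibitory receptors (0.697), glycolysis (0.816), cholesterol synthesis, CD4 identity (0.74), plasma cell (0.0898), dendritic cell (0.113), CD8 and erythroid (0.16; median -9.05, at bound -4.51) lists. Median and mean differed in sign for Th2 (-0.12, 0.19), the naive list (-0.21, 0.03), interferon gamma response (0.12, -0.18) and glycolysis (-0.003, 0.001), and cholesterol synthesis had a median of 0.16 with a downward test.

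In non-Tfh cells Tbx21 was 16.9-fold higher with Tomato (173 ± 13.6 against 10.4 ± 0.0314 RPKM; adjusted p = 0.00753, edgeR). Ifng was 175-fold higher, at 268 ± 39.6 against 1.56 ± 0.380 RPKM (adjusted p = 0.0312). Klrg1, an effector T and NK cell receptor gene, rose by 8.35 ± 1.13, Ifitm1 by 4.01 ± 0.54, Nkg7 by 4.0 ± 0.30, Abhd4 by 3.97 ± 0.46, Klrk1 by 3.53 ± 0.52 and Serpina3g by 3.38 ± 0.41. The largest falls were those of Emilin2 (-8.17 ± 1.16), Il1b (-7.92 ± 0.88), Plbd1 (-7.33 ± 1.03), Tmem38b (-6.81 ± 0.98) and Cybb, an oxidase gene of phagocytes (-4.04 ± 0.59). Lyz2 fell by 3.43 on the log2 scale, from 923 ± 35.5 RPKM in Tomato- to 84.4 ± 29.0 RPKM in Tomato+ cells, and the lipid carrier gene Apoe fell from 303 ± 68.2 to 37.6 ± 7.21 RPKM. Cxcr5 (-1.30 ± 0.36, adjusted p = 0.309), Bcl6 (-0.18 ± 0.26) and Pdcd1 (0.54 ± 0.27) did not pass; of these, Cxcr5 passed with DESeq2. In all, 39 of 11746 genes changed, 24 higher and 15 lower. The count was 8 without Tomato+ replicate 1, 5 without Tomato+ replicate 2, 37 without Tomato- replicate 1 and 5 without Tomato- replicate 2. It was 3 with the 4 compared libraries alone and 6 without the Tomato- replicate 2 libraries of both populations. With all 8 libraries limma called 71 genes and DESeq2 554. Nkg7, Lgals1 and Lyz2 passed in all 4 fits that left out 1 library, Tbx21 in 3 and Ifng, Klrg1, Klrk1, Emilin2 and Plbd1 in 0. Of 25 named genes that passed, 14 passed in none of these fits.

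Of the Th1 genes 7 of 30 rose with Tomato in non-Tfh cells (adjusted over the list alone, 16), among them Bhlhe40, a regulator of T cell cytokine production (1.54 ± 0.16). Of the non-Tfh effector and migration genes 7 of 20 rose (over the list alone, 14 rose and 1 fell), such as Lgals1 (2.52 ± 0.18), S100a4 (1.95 ± 0.23) and the intermediate filament gene Vim (2.0 ± 0.25). Among B cell markers 4 of 16 fell (over the list alone, 4), which macrophages and dendritic cells also express: the MHC class II genes H2-Ab1 (-2.37 ± 0.27), H2-Aa (-2.18 ± 0.29), H2-Eb1 (-2.44 ± 0.34), and Cd74, which encodes the invariant chain. The list's median was 0.12 (at bound 0.06) and its mean 0.03, while the camera test went downward. The B cell gene Cd79a was at 39.4 ± 15.5 RPKM in Tomato+ and 55.9 ± 8.34 RPKM in Tomato- cells. Macrophage and monocyte markers fell in 2 of 15 cases (over the list alone, 3), Lyz2 and Cybb, and 14 of the 15 had negative values. S100a8 was at 263 RPKM in Tomato- replicate 2 and 0.945 RPKM in replicate 1, and at 68.3 RPKM in Tomato+ replicate 1. Camera called 11 lists: Th1 (median 1.72), non-Tfh effector (1.43), NK markers (4.02, at bound 3.85), cell cycle (0.995) and immediate early genes (0.38) upward, and Tfh (-0.63), Th17 (-1.18), naive (-0.82), B cell, macrophage (-2.60) and neutrophil markers (-7.52, at bound -3.79) downward. Calls were lost at adjusted p with an estimated correlation of 0.0517 for Tfh, 0.0603 for B cell markers, 0.132 for immediate early genes, 0.144 for cell cycle, 0.181 for naive, 0.189 for Th17 and 0.374 for neutrophil markers. The Th1 (adjusted p = 0.00469), non-Tfh effector and macrophage (0.0167 each) and NK (0.0222) lists held with an estimated correlation. Without Tomato+ replicate 2, 7 lists were called in place of 11.

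Within those lists Il6ra (-1.57 ± 0.22) was the one Tfh gene that fell with Tomato in non-Tfh cells, Dusp2 (2.20 ± 0.28), a phosphatase gene induced by activation, the one immediate early gene that rose, and Klrk1 the one NK marker that rose. Over the list alone 9 Tfh, 5 naive and 2 Th17 genes fell, 3 cell cycle and 2 NK genes rose, and 7 immediate early genes rose with 4 falling. The glycolysis list was not called (camera adjusted p 0.0687), although Pdk1, a kinase that limits pyruvate oxidation, fell by 3.61 on the log2 scale (-3.61 ± 0.49). The other lists not called were Th2 (0.515), Treg (0.224), type I interferon response (0.224; median -0.36), interferon gamma response (0.443), inhibitory receptors (0.273), cholesterol synthesis (0.917), CD4 identity (0.351), plasma cell (0.0647), dendritic cell (0.224; median -0.01, at bound -0.74), CD8 (0.612) and erythroid (0.273). Over the list alone 2 Th2, 2 glycolysis, 1 inhibitory receptor and 1 plasma cell gene rose, and 1 gene fell in each of the Th2, glycolysis, cholesterol and dendritic lists.

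**Figure D2:**
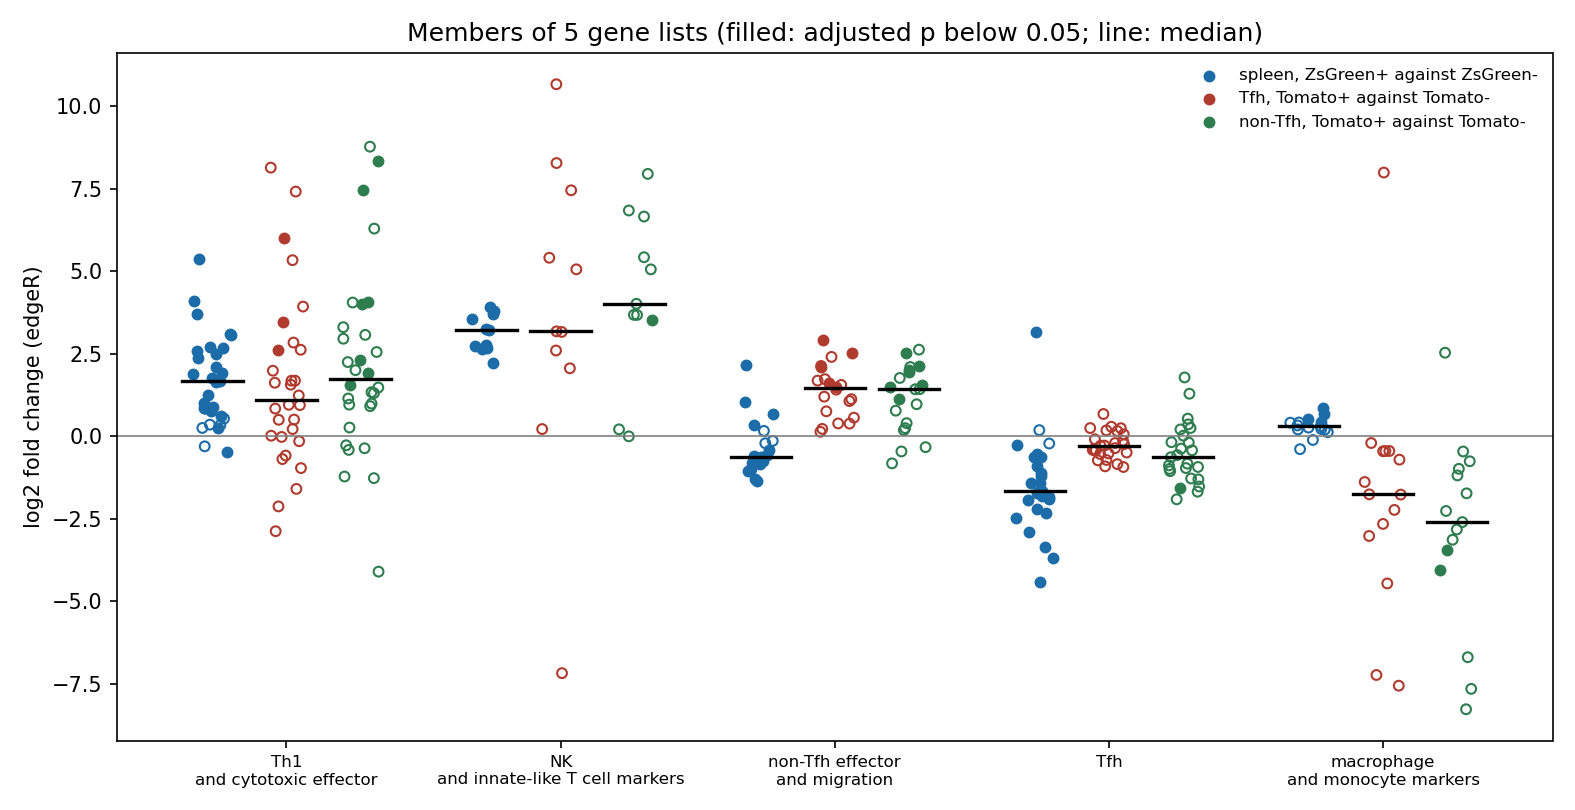
Log2 fold changes fitted by edgeR for the members of 5 fixed gene lists in 3 comparisons, spleen ZsGreen+ against ZsGreen- and Tomato+ against Tomato- in Tfh and in non-Tfh cells; filled points passed an adjusted p of 0.05 and lines mark medians. The median of the non-Tfh effector list was -0.62 in the spleen, 1.46 in Tfh cells and 1.43 in non-Tfh cells, and values of genes with a group at 0 depend on the prior count.

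Tfh cells were then set against non-Tfh cells that share the mark of present or past T-bet expression. The sort used CXCR5 and PD1, so higher Cxcr5 and Pdcd1 in Tfh cells is not an independent result. Among Tomato+ cells the Tfh regulator gene Ascl2 was higher in Tfh cells by 7.29 ± 0.78 (45.2 ± 9.47 against 0.265 ± 0.149 RPKM), Sostdc1 by 3.32 ± 0.29, Fam43a by 3.06 ± 0.34, the transcription factor gene Tox by 2.17 ± 0.26, Smtn by 2.03 ± 0.22, Rgs10 by 1.69 ± 0.21 (log2 fold change 1.685) and Fos by 1.17 ± 0.13. The gut-homing integrin gene Itgb7 (-1.45 ± 0.17) and Selplg (-1.27 ± 0.15) were lower. Bcl6 (4.23-fold higher) and Cxcr5 (6.91-fold higher), each with adjusted p = 0.0521, and Pdcd1 (3.56-fold higher, adjusted p = 0.0756) did not pass, and neither did Tbx21 (-1.21 ± 0.32, adjusted p = 0.34) or Ifng (-1.68 ± 0.79). Bcl6, Cxcr5 and Pdcd1 passed with limma, DESeq2, no filter and the filter at 5 RPKM, Bcl6 and Cxcr5 also with RLE factors, and Tbx21 with DESeq2. These 9 genes, 7 higher and 2 lower, were all that passed among 11746 (edgeR). The count was 0 with edgeR without Tfh Tomato+ replicate 1 (571 genes at an unadjusted p below 0.05) and without non-Tfh Tomato+ replicate 1 (702) or replicate 2 (750), and 1 without Tfh Tomato+ replicate 2. It was 0 with the 4 libraries alone (1115 at an unadjusted p below 0.05) and without both Tomato- replicate 2 libraries (1083). With all 8 libraries limma called 29 genes and DESeq2 410. Sostdc1 passed in 1 of the 4 fits that left out 1 library and the other 8 genes in 0. Of the Tfh list 3 of 25 genes rose (adjusted over the list alone, 17 rose and 1 fell), of the non-Tfh effector list 2 of 20 fell (over the list alone, 15) and of the immediate early list Fos rose (over the list alone, 3 rose and 3 fell).

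Camera called 8 lists among Tomato+ cells: Tfh (median 1.47), inhibitory receptors (0.71, mean -0.25) and macrophage markers (0.94, at bound 1.01) upward, and Th1 (-0.94), non-Tfh effector (-1.04), Treg (-0.64), naive (-0.85) and interferon gamma response genes (-0.34, adjusted p = 0.0428) downward. Calls were lost at adjusted p with an estimated correlation of 0.136 for Treg and naive, 0.196 for interferon gamma response and inhibitory receptors and 0.24 for macrophage markers. The Tfh (0.00713), Th1 and non-Tfh effector (0.0118 each) lists held with an estimated correlation. The calls of the Tfh and inhibitory receptor lists are not independent of the gate on CXCR5 and PD1. No list was tested without the genes of these markers. Adjusted over the list alone, 7 Th1 genes fell, 5 Treg and 5 naive genes fell with 1 of each rising, 1 interferon gamma response gene fell, and 5 inhibitory receptors and 2 macrophage markers rose; over all genes none of these passed. Without Tfh Tomato+ replicate 2, 4 lists were called. In lists not called, 1 Th2, 1 glycolysis and 1 cholesterol gene rose and 1 Th17, 1 type I interferon and 1 cholesterol gene fell over the list alone. Not called were Th2 (0.893; median -0.20, test direction up), Th17 (0.883), cell cycle (0.0898), immediate early (0.359), type I interferon (0.43), glycolysis (0.168), cholesterol synthesis (0.899; median -0.02, mean 0.11), CD4 identity (0.729), B cell (0.819), plasma cell (0.182), dendritic (0.2), neutrophil (0.819; median 1.97, at bound -4.20), CD8 (0.729), NK (0.419; median 0.13, mean -0.22) and erythroid (0.899; median -2.32, mean 0.86, at bound 2.68) lists.

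Among Tomato- cells Bcl6 was 4.41-fold higher in Tfh than in non-Tfh cells (120 ± 27.1 against 26.3 ± 7.45 RPKM) and Pdcd1 5.48-fold higher (631 ± 119 against 111.0 ± 29.8 RPKM). Cxcr5 was 3.07-fold higher without passing (adjusted p = 0.219, edgeR), and passed with DESeq2. Abcc3 rose by 7.19 ± 0.997, Cxxc5 by 7.18 ± 0.90, Nanos1 by 7.03 ± 0.87, Ascl2 by 6.90 ± 0.76, Abhd4 by 4.96 ± 0.48 and Sostdc1 by 2.09 ± 0.28. Emp1 (-7.09 ± 0.74), Cish (-2.99 ± 0.31), the egress receptor gene S1pr1 (-2.68 ± 0.19), Rasgrp2 (-2.52 ± 0.31), Ahnak (-2.29 ± 0.25) and Selplg (-1.64 ± 0.15) were lower in Tfh cells. Tbx21 (0.24 ± 0.32) and Ifng (1.84 ± 0.84, adjusted p = 0.576) did not pass. Ifng was at -0.63 without Tfh Tomato- replicate 1 and passed without Tfh Tomato- replicate 2 (log2 fold change 2.70). In all 21 genes changed, 10 higher and 11 lower. The count was 6 without Tfh Tomato- replicate 1, 12 without Tfh Tomato- replicate 2, 11 without non-Tfh Tomato- replicate 1 and 8 without non-Tfh Tomato- replicate 2. With edgeR it was 0 with the 4 compared libraries alone (883 genes at an unadjusted p below 0.05) and 0 without both replicate 2 libraries (851). With all 8 libraries limma called 43 genes and DESeq2 539. Abhd4, S1pr1 and Selplg passed in all 4 fits that left out 1 library, Cish in 3, Pdcd1 and Emp1 in 2, Bcl6, Ascl2, Nanos1, Sostdc1 and Ahnak in 1 and Abcc3, Cxxc5 and Rasgrp2 in 0.

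Of the Tfh list 5 of 25 genes rose among Tomato- cells (adjusted over the list alone, 12 rose and 1 fell) and of the non-Tfh effector list 4 of 20 fell (over the list alone, 13). S1pr1 was the one naive gene to fall (over the list alone, 6), and Pdcd1 the one inhibitory receptor to rise (over the list alone, 5). Pdcd1 encodes PD1, by which the cells were sorted, so its rise was set by the gate. The inhibitory receptor list holds this gene and the Tfh list describes the gated cells, so their calls are not independent of the gate. No list was tested without the genes of the sort markers. Camera called 10 lists: Tfh (median 1.62), inhibitory receptors (0.95), glycolysis (0.54) and cell cycle (0.52) upward, and non-Tfh effector (-1.21), naive (-1.85), Treg (-0.63), Th17 (-0.64), interferon gamma response (-0.67) and Th1 genes (-0.18, at bound -0.23) downward. Calls were lost at adjusted p with an estimated correlation of 0.0723 for Treg and interferon gamma response, 0.0812 for glycolysis, 0.148 for Th1 and 0.362 for Th17 and cell cycle. The Tfh and non-Tfh effector (0.0173 each), naive and inhibitory receptor (0.0467 each) lists held with an estimated correlation. Over the list alone 5 Treg, 2 interferon gamma response and 5 Th1 genes fell, 2 Th1 and 4 glycolysis genes rose and 1 glycolysis gene fell, and over all genes none of these passed. In lists not called, 1 Th2 and 3 immediate early genes rose over the list alone. Not called were Th2 (0.192; median 0.17, mean -0.01), immediate early (0.317), type I interferon (0.943; median -0.003, mean 0.55), cholesterol synthesis (0.943; median -0.10, test direction up), CD4 identity (0.943; median 0.06, test direction down), B cell (0.39; median -0.66, mean 0.45), plasma cell (0.317), macrophage (0.614), dendritic (0.259; median -0.99, mean 0.21), neutrophil (0.895; median 0.15, mean -1.36), CD8 (0.943), NK (0.943; at bound 0.01) and erythroid (0.614) lists.

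Whether the Tomato difference itself differed between Tfh and non-Tfh cells was tested as an interaction. With edgeR 0 of 11746 genes passed, with 746 at an unadjusted p below 0.05; DESeq2 called 143 and limma 0. The smallest adjusted p was 0.677, shared by 7 genes that include Emp1 (5.87 ± 0.87), Abhd4 (-3.80 ± 0.60), S1pr1 (1.58 ± 0.25), Apoe (2.99 ± 0.49) and Tmem38b (6.99 ± 1.19). Tbx21 (-1.45 ± 0.45) and Ifng (-3.52 ± 1.15), each with adjusted p = 0.774, Cxcr5 (1.17 ± 0.50), Bcl6 (-0.06 ± 0.37) and Pdcd1 (-0.62 ± 0.38) did not pass. With DESeq2 Ifng, Emp1, Abhd4, S1pr1, Apoe and Tmem38b passed. Camera called the Th1 list alone (median -0.62, adjusted p = 0.0296), lower in the Tfh than in the non-Tfh Tomato difference. Its adjusted p = 0.498 with an estimated correlation of -0.0189, below the preset 0.01, in a fit with 4 residual degrees of freedom. Of the 8 fits that left out 1 library, the fit without Tfh Tomato- replicate 1 kept this call, and the call was lost without any of the other libraries. The other 22 lists had camera adjusted p values from 0.0541 for the naive list to 0.95 for the dendritic, cholesterol and plasma cell lists.

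Genes that rose with Tomato in both populations numbered 9, where independent lists share 0.0245 (Fisher's exact test, two-sided, adjusted p = 2.94e-22 over 12 overlap tests). They were Cish, Crip1, Furin, Ifngr1, Lgals1, Lgals3, Nkg7, Selplg and Tbx21. Il1b was the one gene that fell in both (expected 0.00128, adjusted p = 0.00383), and no gene moved in opposite directions. The shared fall of Il1b was kept without either Tomato- replicate 1 library and lost without any of the other libraries. Both comparisons used one estimate of spread per gene from the 8 libraries, which by itself favours the same genes. Leaving out 1 library gave from 1 shared gene (without Tfh Tomato- replicate 2) to 5 (without Tfh Tomato+ replicate 2): 2 without Tfh Tomato+ replicate 1, 3 without Tfh Tomato- replicate 1 or non-Tfh Tomato- replicate 2, and 4 without any of the other three libraries. Of genes higher in spleen ZsGreen+ cells, 7 also rose with Tomato in Tfh cells (expected 1.37, adjusted p = 0.000476) and 13 in non-Tfh cells (expected 2.75, adjusted p = 2.42e-06), among them Ifng, Bhlhe40, Cxcr6 and Klrk1. Tbx21 was among the shared genes here as well. Each of these sorts used a reporter or mark of T-bet expression, so its place in the overlaps is not an independent result. In the other direction 8 genes that fell in spleen ZsGreen+ cells rose with Tomato in non-Tfh cells (expected 3.19, adjusted p = 0.0235): Abhd4, Crip1, Klrg1, Lgals1, S100a10, S100a4, Slamf1 and Vim. Crip1, Emp1 and Lgals1 did so in Tfh cells (3 genes, expected 1.59, adjusted p = 0.355). That overlap passed with limma calls (7, expected 2.68, adjusted p = 0.0217) and DESeq2 calls (34, expected 19.4, adjusted p = 0.00154). With calls at an adjusted p below 0.1 it did not pass (7, expected 3.91, adjusted p = 0.143). Lower in the spleen and in non-Tfh Tomato+ cells were Galnt6, Il6ra, Smtn and Tmem38b (4, expected 1.99, adjusted p = 0.256). This shared fall passed with limma calls (10, expected 3.46, adjusted p = 0.00286) and DESeq2 calls (75, expected 32.7, adjusted p = 4.52e-12). With calls at an adjusted p below 0.1 it passed as well (10, expected 4.76, adjusted p = 0.0377). Higher in the spleen but lower in non-Tfh Tomato+ cells were Lyz2 and Plbd1 (2, expected 1.72). These 2 became 7 without spleen ZsGreen+ replicate 2 and 0 without spleen ZsGreen+ replicate 1. The 13, 8 and 7 shared genes became 4, 1 and 2 without the matching Tomato+ replicate 1, and 3, 1 and 4 without Tomato+ replicate 2. Without the matching Tomato- replicate 1 they were 13, 3 and 3, and without Tomato- replicate 2 they were 3, 1 and 1.

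Accessible chromatin was given as islands called by the authors in each DNase library on mouse build mm9, per the submitters' processing notes. In Tfh cells the Tomato+ libraries held 14084 and 15374 islands and the Tomato- libraries 18742 and 17531. In non-Tfh cells the Tomato+ libraries held 20460 and 21222 and the Tomato- libraries 18061 and 14980. Over both populations the island number differed by 456.5 between Tomato+ and Tomato- (exact permutation test, two-sided, p = 0.857) and by -2248 between Tfh and non-Tfh cells (exact p = 0.257). The latter was -1465 without Tfh Tomato+ replicate 1, -1401 without non-Tfh Tomato+ replicate 2 and -3482 without non-Tfh Tomato- replicate 2. Covered length was 40.02 ± 2.23 Mb in Tfh and 36.1 ± 2.84 Mb in non-Tfh libraries (SD, n = 4; exact p = 0.0857), and 38.2 ± 3.76 Mb in Tomato+ against 37.9 ± 3.01 Mb in Tomato- libraries (exact p = 0.914). With scores above the median of each library the Tfh minus non-Tfh difference fell from 3.91 to 1.38 Mb (exact p = 0.2). Within each population covered length overlapped between Tomato+ (38.67 and 41.58 Mb in Tfh, 39.75 and 32.88 Mb in non-Tfh cells) and Tomato- libraries (42.23 and 37.61, and 35.44 and 36.37 Mb). The Tomato difference in island number changed sign without either non-Tfh Tomato+ replicate (-435.2 and -689.2) and without non-Tfh Tomato- replicate 2 (-326.3). The Tomato difference in covered length changed sign without Tfh Tomato+ replicate 2 (-0.811 Mb) and without non-Tfh Tomato+ replicate 1 (-0.203), Tomato- replicate 1 (-0.516) or Tomato- replicate 2 (-0.206). The share of covered 200-bp bins held by both of a pair of libraries (Jaccard index) was 0.505 ± 0.0141 within groups and 0.471 ± 0.0230 between groups (one-sided exact permutation test over 105 pairings, p = 0.00952). The difference of 0.0343 between these means became 0.019 without non-Tfh Tomato+ replicate 2. The Tfh Tomato+ replicates shared 0.493, less than Tfh Tomato+ replicate 2 and Tfh Tomato- replicate 2 (0.502). The non-Tfh Tomato- replicates shared 0.496, less than non-Tfh Tomato- replicate 2 and Tfh Tomato- replicate 2 (0.5005). In the other groups the replicates were more alike than any pair with another group (0.507 in Tfh Tomato-, 0.524 in non-Tfh Tomato+).

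Merging the islands gave 25755 regions, of which 10598 held an island in all 8 libraries and 4501 in 1 library. In Tfh cells 133 regions were private to Tomato+ (an island in both its libraries and in neither Tomato- library) and 1169 to Tomato-. In non-Tfh cells 2201 were private to Tomato+ and 195 to Tomato-. The other ways to split the same 4 libraries into pairs gave at most 414 regions in Tfh and 447 in non-Tfh cells. Among Tomato+ cells 233 regions were private to Tfh and 3173 to non-Tfh cells (other splits at most 254), and among Tomato- cells 1000 and 361 (other splits at most 578). With the 10000 highest scores of each library the counts were 245 and 224 in Tfh cells, below the 289 of another split, and 646 and 484 in non-Tfh cells, above the 191 of other splits. Tfh and non-Tfh cells then held 615 and 694 private regions in Tomato+ cells (other splits at most 182) and 353 and 420 in Tomato- cells (at most 232), where the larger count changed sides. Where an island had to cover at least 0.5 of a region, the counts were 974 and 1056 in Tfh cells and 1740 and 1105 in non-Tfh cells, with other splits at most 843 and 1134. Between populations they were 1794 and 1944 in Tomato+ and 1293 and 761 in Tomato- cells (other splits at most 1025 and 934). With 3 ways to split 4 libraries no p below 0.05 can be reached, and none is given. By the authors' score, the highest region private to non-Tfh Tomato+ against Tomato- cells lay on chromosome 4 from 102530601 to 102533600 (mean score 279), followed by chromosome 1 from 54717401 to 54718800 (272.5) and chromosome 5 from 136011401 to 136015200 (246.6). The highest region private to Tfh Tomato- cells lay on chromosome 7 from 46555001 to 46562800 (mean score 110.0), that private to Tfh Tomato+ cells on chromosome 2 from 166486801 to 166492800 (117.6), and that private to non-Tfh Tomato- cells on chromosome 7 from 56589801 to 56592200 (99.1). Private refers only to the groups compared: in the order named, these regions held islands in 5, 6 and 5 of all 8 libraries. Between populations, the highest region private to non-Tfh Tomato+ against Tfh Tomato+ cells lay on chromosome 10 from 111435601 to 111440800 (261.8), and the highest private to Tfh Tomato- against non-Tfh Tomato- cells on chromosome 1 from 184691401 to 184696200 (159.7). Which genes lie at these regions, and the Ifng locus named in the series title, were not analysed here.

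**Figure D3:**
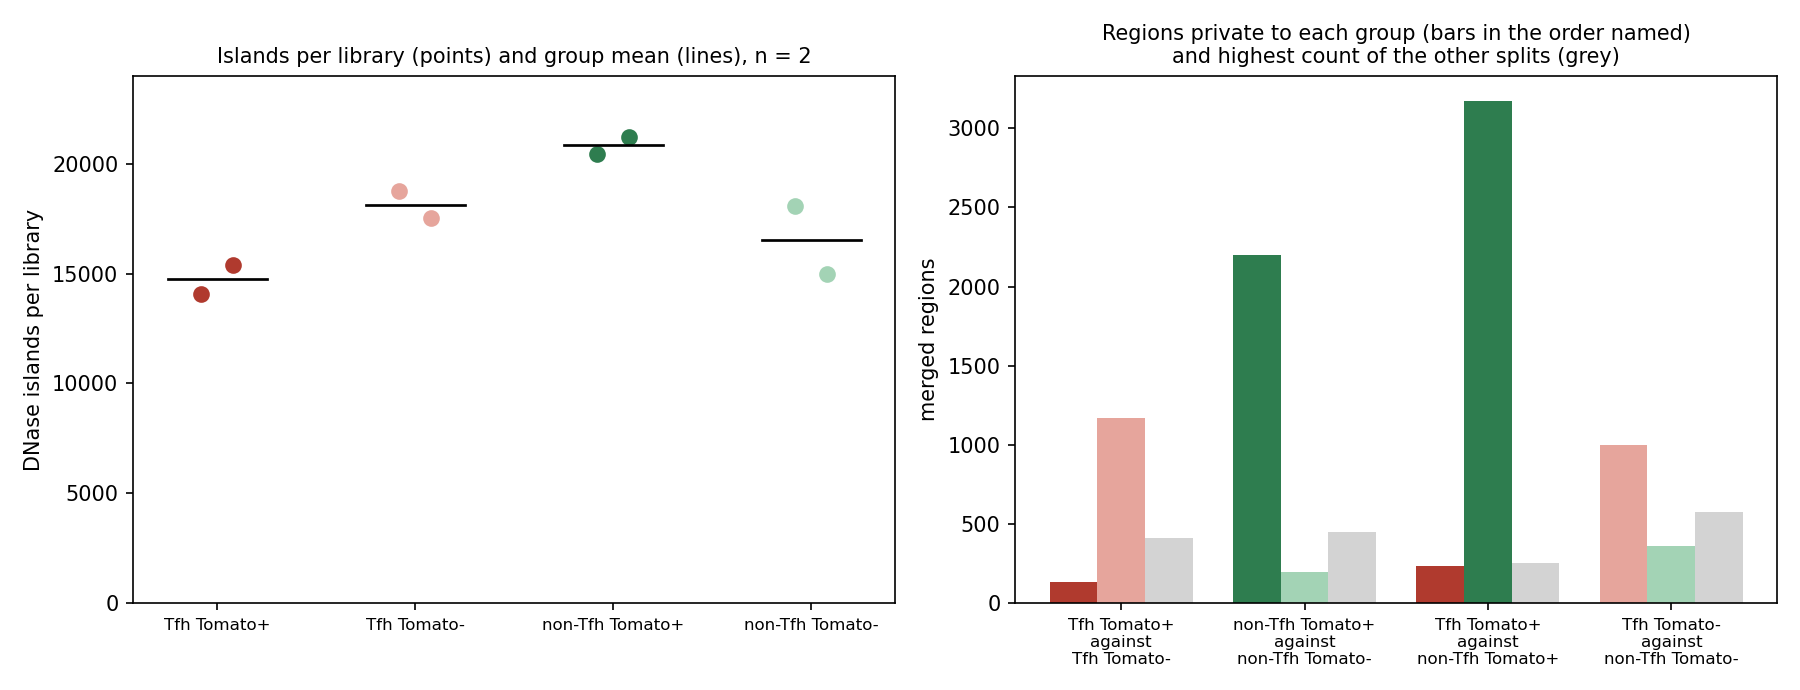
Left, DNase islands in each library (points) with the mean of each group (lines, n = 2); right, merged regions private to each group of a pair, in the order named under the bars, with the highest count of the other splits of the same 4 libraries in grey. The bars of non-Tfh Tomato+ cells reach 2201 against Tomato- and 3173 against Tfh Tomato+ cells.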

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

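The tests of macrophage and B cell markers and of weak islands were chosen after the result was seen, and those of sequencing depth, of captured molecules and of island number before it. The Tomato difference in the number of DNase islands went opposite ways in the 2 populations: both Tomato+ libraries lay below both Tomato- libraries in Tfh cells and above them in non-Tfh cells, a difference of -7728 islands (exact permutation test, two-sided, p = 0.0556, the smallest that 36 arrangements can give). Covered length overlapped between Tomato+ and Tomato- libraries in both populations. Median island width was 2400 bp in both Tfh Tomato+ and 2000 bp in both Tfh Tomato- libraries. In non-Tfh cells it was 1800 and 1400 bp with Tomato and 1800 and 2200 bp without. Island number alone therefore does not measure how much chromatin was open. The Th1 list differed in its Tomato response between Tfh and non-Tfh cells by camera (adjusted p = 0.0296; median -0.62), with adjusted p = 0.498 with an estimated correlation and 0.0728 by fry.

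In Tfh cells 1169 regions were private to Tomato- and 133 to Tomato+, and in non-Tfh cells 2201 to Tomato+ and 195 to Tomato-; with scores above each library's median, which leaves more islands where more were called, they were 684 and 51 (other splits at most 218) and 1183 and 107 (at most 214). With 10000 islands in each library the Tfh counts became 224 in Tomato- and 245 in Tomato+, not above the 289 of another split, and the non-Tfh counts 646 in Tomato+ and 484 in Tomato- against 191, which met the bound set for different numbers of islands called per library, but equal numbers hold the counts of a pair near each other by construction, a reason added after the values were seen, so this cause cannot be told apart in either population. Weak islands as the whole cause are argued against in non-Tfh cells. There 170 of the 2201 regions private to Tomato+ and 0 of the 195 private to Tomato- had islands above the median score of both libraries (0 in the other splits). This median is taken within each library, so more islands lie above it where more were called, and the difference between the 2 groups is not weighed by it. In Tfh cells these were 5 private to Tomato- and 1 to Tomato+ (at most 2 in the other splits), too few to decide. As a part of the cause weak islands cannot be told apart, since median score percentiles of private regions were up to 20.5 in Tfh Tomato- libraries and 29 in non-Tfh Tomato+ libraries, the latter above the bound of 25 set for weak islands, and low in the opposite groups as well (14.9 and 18.9, and 18.3 and 12). A difference in chromatin that goes with present or past T-bet expression stays open and was not tested.

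Transcripts of the MHC class II genes and Cd74 had median log2 fold changes of -1.35 in Tfh and -2.28 in non-Tfh cells (Tomato+ against Tomato-), and over all genes 4 of them passed in non-Tfh and 0 in Tfh cells. Of 15 macrophage and monocyte markers 14 were below 0 in each population (medians -1.76 and -2.6), so macrophages or monocytes, or their RNA, in the Tomato- sorts are a candidate source, and all 15 were also expressed enough to be tested in the spleen CD4 libraries. Lyz2 was the most abundant of these markers, at 923 ± 35.5 RPKM in non-Tfh Tomato- and 84.4 ± 29.0 RPKM in Tomato+ cells. The sort for tetramer-positive CD4 cells is a gate meant to remove macrophages, but Lyz2 transcripts were in the sorted samples at these levels. B cells as the whole source are argued against by their other 12 markers, whose median was 0.589 in non-Tfh cells (lower quartile -0.0239), although it was -0.2 in Tfh cells. Dendritic cells, which also express these genes, were not tested as a source and stay open. The median of their marker list was -1.16 in Tfh cells and -0.009 (at bound -0.744) in non-Tfh cells, and camera called it in neither. Activated T cells with another history of T-bet expression were not tested as a source. As the whole source of both patterns they would leave the 14 lower macrophage and monocyte markers of each population without an account. As a part of the source of the MHC class II transcripts they stay open.

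Replicates of the lymph node RNA libraries spread far more than those of the spleen (coefficients of variation 0.908 and 0.0867). Lower sequencing depth is argued against, since spleen counts thinned to 13169783 reads gave 0.0809. Few captured RNA molecules may account for it: squared variation fell with mean count with a log10 slope of -0.8 ± 0.0221 (SE), but the spleen slope of -0.558 ± 0.0338 also passed the bound, so the slope alone separates the tissues little. In the genes of lowest count the squared variation was 2.5 in the lymph node and 0.127 in the spleen. Differences between animals stay open and were not tested.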

How the results depend on the processing

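Leaving out libraries for lists, overlaps and island statistics, the longest transcript row and leaving out both Tomato- replicate 2 libraries were chosen after the data were seen. The spleen count stayed within 1.5 times under every alternative (2150 to 3681), and RLE factors, the longest transcript and, but for the Tfh Tomato and lymph node Tomato+ comparisons, the 5 RPKM filter moved no count by more. Lymph node counts are given in the order Tfh Tomato, non-Tfh Tomato, Tfh against non-Tfh in Tomato+ and in Tomato-: limma gave 29, 71, 29 and 43; its pseudocount of 0.1 gave 21, 59, 23 and 26; DESeq2 gave 262, 554, 410 and 539 (interaction 143); no filter gave 25, 65, 49 and 52; the 5 RPKM filter gave 20, 48, 18 and 29. The 4 compared libraries alone gave 0, 3, 0 and 0 with edgeR (729, 988, 1115 and 883 at an unadjusted p below 0.05). Leaving out both Tomato- replicate 2 libraries gave 0, 6, 0 and 0 (759, 899, 1083 and 851). Fewer samples enter both fits. For the other settings the cause was not tested. On data simulated once for the Tfh Tomato comparison, with dispersions from edgeR's own trend, 96 of the 160 DESeq2 calls were false. That setting favours edgeR, so it does not decide why DESeq2 called more genes here. Leaving out 1 library gave 2 to 8, 5 to 37, 0 to 1 and 6 to 12. The replicate numbers do not pair the samples by any label, and same-number correlations were 0.119 in the spleen and -0.0134 to 0.0284 in the lymph node. The replicate block gave 3359 in the spleen and 12, 23, 1 and 22 in the lymph node, and 2 lists for the interaction.

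With an estimated correlation 0 lists were called in the spleen, 4, 4, 3 and 4 in the lymph node comparisons and 0 for the interaction; fry called 12, then 5, 8, 3 and 8, and 0. Leaving out 1 library gave 7 to 11 lists in non-Tfh cells, 4 to 7 in Tomato+ and 0 to 2 for the interaction. Log2 fold changes that did not pass changed sign without 1 library in Tfh Tomato for Bcl6 (-0.46 to 0.0093), Cxcr5 (-0.41 to 0.14) and Pdcd1 (-0.28 to 0.11), in non-Tfh Tomato for Bcl6 (-0.42 to 0.13), in Tomato- for Ifng (-0.63 to 2.70) and in the interaction for Bcl6 (-0.36 to 0.19). No named gene that passed changed sign under any alternative run. Calls of named genes were lost in 4 of 284 fits without 1 library in the spleen, 29 of 44 for Tfh Tomato, 78 of 100 for non-Tfh Tomato, 35 of 36 in Tomato+ and 38 of 64 in Tomato-.

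Genes higher with Tomato in both populations numbered 16 at an adjusted p below 0.1, 56 with DESeq2 and 17 with limma (1 to 5 without 1 library), lower in both 3, 29 and 3 (0 to 1). Higher in Tfh and lower in non-Tfh cells were 1 with DESeq2, and the reverse 3 with DESeq2 and 1 with limma. Shared by higher spleen ZsGreen+ and higher Tfh Tomato+ were 11, 48 and 14 (1 to 7), lower in both 11 with DESeq2, higher then lower 1, 7 and 1 (0 to 1), and lower then higher 7, 34 and 7 (0 to 4). For non-Tfh cells these were 77 with DESeq2 and 20 with limma (3 to 14) for higher in both, 10, 75 and 10 (0 to 5) for lower in both, 9, 32 and 7 (0 to 7) for higher then lower, and 62 with DESeq2 (1 to 9) for lower then higher.

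The Tomato difference in island number ranged from -689.2 to 1690 and in covered length from -0.811 to 2.09 Mb without 1 library. The Tfh minus non-Tfh difference in covered length, 3.91 Mb, was 1.38 Mb (exact permutation p = 0.2) with scores above the median and 4.16 Mb with the 10000 highest scores. Regions private to Tomato+ and Tomato- numbered 245 and 224 in Tfh and 646 and 484 in non-Tfh cells with the 10000 highest scores, where the island number is fixed and gives no value, and 51 and 684, and 1183 and 107, with scores above the median. Private to Tfh and non-Tfh cells were 615 and 694 in Tomato+ and 353 and 420 in Tomato- with the 10000 highest scores, and 105 and 1708, and 525 and 215, above the median. With coverage of at least 0.5 of a region the counts were 974 and 1056, 1740 and 1105, 1794 and 1944, and 1293 and 761. Without 1 library they rise because fewer libraries must share a call: 314 to 689 and 1827 to 3366 in Tfh, 2685 to 3947 and 445 to 1287 in non-Tfh, 408 to 770 and 3833 to 5096 in Tomato+, and 1476 to 2931 and 629 to 1844 in Tomato- cells. The island alternatives for the Ifng locus and for regions near changed genes, and their other windows, were not run. Thinning the spleen counts to 13169783 reads left a coefficient of variation of 0.0809, and calls were not counted on the thinned data. On simulated data edgeR recovered 16.4% of 4-fold changes for Tfh Tomato and 17.9% for non-Tfh Tomato.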

Other observations

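No tests are reported here, and the genes were chosen after their values were seen. Immediate early genes, which are induced within minutes by receptor signals or handling of cells, stood at different levels in the spleen and the lymph node libraries. Junb averaged 234 ± 25.8 RPKM in spleen ZsGreen- and 262 ± 7.85 RPKM in ZsGreen+ cells, and from 4318 ± 30.3 RPKM in non-Tfh Tomato+ to 6429 ± 319 RPKM in Tfh Tomato- cells (SD, n = 2). Fos averaged 16.3 ± 1.301 and 12.1 ± 1.96 RPKM in the spleen groups, and from 732 ± 2.55 RPKM in non-Tfh Tomato+ to 2178 ± 123 RPKM in Tfh Tomato- cells. Dusp1, a phosphatase gene of the same kind, averaged 37.4 ± 5.08 and 45.7 ± 0.913 RPKM in the spleen groups and 2526 ± 389 RPKM in Tfh Tomato+ cells. As a share of gene counts Dusp1 was 0.766 and 0.633% in the Tfh Tomato+ libraries and 1.015 and 0.706% in Tfh Tomato- libraries. In non-Tfh cells it was 0.248 and 0.258% with Tomato and 0.385 and 0.448% without. The tissues differ in mouse strain, immunization and sort, so these levels are set side by side without a test.

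Cxcr6, a receptor gene of tissue-resident and effector T cells, was highest in spleen ZsGreen+ cells (606 ± 106 RPKM) and non-Tfh Tomato+ cells (495 ± 57.2 RPKM), with 262 ± 26.4 RPKM in Tfh Tomato+, 134 ± 34.9 RPKM in non-Tfh Tomato-, 87.7 ± 6.25 RPKM in Tfh Tomato- and 34.1 ± 3.13 RPKM in spleen ZsGreen- cells. Klrk1 stood at 24.1 ± 0.321 RPKM in spleen ZsGreen+, 23.4 ± 7.66 RPKM in Tfh Tomato+ and 36.5 ± 1.81 RPKM in non-Tfh Tomato+ cells, and between 2.004 and 3.83 RPKM in the other groups.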
